A study of Homo sapiens with 6 samples.

How the data were processed

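RNA sequencing of polyadenylated RNA was analysed for 3 control and 3 knockdown libraries of THP-1 macrophages, grouped by the sample titles. Per the submitters' processing notes, Salmon 0.11.2, DESeq2 and the genome build hg38 were used, with no roles given. The deposited table holds expected counts per gene symbol, in whole numbers (100% of values), for 17042 genes and 6 libraries. Its lowest row sum over the 6 libraries was 10, so genes with fewer counts were not analysed here. Counts that Salmon assigns are estimates and split reads between genes that share sequence, and such genes are named as uncertain. How the authors rounded the estimates, and whether strand was used, is not given in the sources used here. Library totals ran from 10450043 to 14181343 counts, and 3 counts, taken as the floor for a library at 0, came to between 0.21 and 0.29 CPM.

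The counts were used as deposited. Genes were tested with edgeR 4.0.16 quasi-likelihood (TMM factors, filterByExpr by group, group as the only term, two-sided, Benjamini-Hochberg adjustment, threshold 0.05), which kept 13405 genes. The standard error of a log2 fold change is its size divided by the square root of F, an approximation. CPM values use the TMM factors. The 22 gene lists, 496 entries, were fixed with the tests and the naming rule before the data were examined. Of the entries, 464 were in the table, 16 of them under an older symbol. Lists with at least 5 tested members (20 lists) were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01, and also with an estimated correlation and with fry. Other tools were R 4.3.3, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

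Positions, gene types, overlaps and 3' UTRs came from GENCODE 29 on GRCh38, which matched 16651 of the 17042 symbols by a unique name. The table holds 1945 clone-derived names, treated as symbols, and no row named RP11-184M15.1. The planned value of RP11-184M15.1 and the planned test of its neighbouring genes were therefore not run, and its level is not analysed here.

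The rule for named genes took RP11-184M15.1, then genes past the threshold with a mean log2 CPM of at least 1 and all 3 knockdown values above or all below the 3 control values, 12 per direction with the smallest p, leaving out genes with an identifier only, Y-linked genes and XIST, then up to 4 members of each list with the smallest p among those tested, and then the neighbours of RP11-184M15.1. Of the genes past the threshold, 158 higher and 209 lower met every part of the rule but the limit of 12. Genes named outside the rule are said to be so.

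No libraries of a group were duplicates: chi-square per degree of freedom over genes with at least 20 counts in a pair ran from 1.90 to 6.79. Alternatives were DESeq2's Wald test, RLE and upper-quartile normalization, no filter, a filter of at least 1 CPM in at least 3 libraries, limma-voom, the replicate number as a block, leaving out each library, an adjusted p under 0.01, an absolute log2 fold change of at least 1, and, for the lists, an estimated correlation and fry. DESeq2 and limma-voom do not apply to the list tests. The main, RLE and upper-quartile fits differed by under 0.1 in the median log2 fold change of all genes.

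The tests were run on simulated data first, with 200 of the 13405 genes changed in 5 simulations of knockdown against control. edgeR called 47.2% of genes changed 1.25-fold, 72.8% of those changed 1.5-fold, 80% of those changed 2-fold and 100% of those changed 4-fold, and 8.76% of its calls were unchanged genes (DESeq2, 2.48%). In 20 simulations with the MHC class II list shifted by -0.3, that list passed in 20, and on average 0.2 of the other 19 lists passed. Genes were simulated independently, so these simulations do not cover lists whose members move together. In the real libraries the estimated correlation was 0.37 for the MHC class II list. Over the lists it ran from -0.04 (phagocytic and scavenger receptors) to 0.88 (mitochondrially encoded mRNA).

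Words in 3' UTRs were searched in 11034 genes with a mean log2 CPM of at least 1 and an annotated 3' UTR (the longest per gene, 92.7% of such genes). For each word in at least 30 genes, z is the mean, over carriers, of the rank-normalized signed test statistic after its trend with the length and GC content of the 3' UTR was removed, in units of its standard error, and 1000 permutations of genes gave the range by chance. In 20 simulations on these genes a planted 7-base word came out lowest in 20.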

Results

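Messenger RNA was measured in 6 libraries of THP-1, a human monocytic leukaemia cell line. Per the labels, the cells were turned into macrophages with 100 ng/mL of the phorbol ester PMA for 24 hours and then held with 20 ng/mL interleukin-4 (IL-4) for 24 hours, a cytokine that drives macrophages toward a tissue-repair state. In 3 libraries the long noncoding RNA RP11-184M15.1 had been targeted with small interfering RNA (siRNA), carried into the cells by a lipid reagent before IL-4, and 3 libraries were controls. The labels do not say what the control cells received. The control libraries held 10751517, 12113848 and 10450043 counts and the knockdown libraries 12214767, 14181343 and 12029360. Mitochondrially encoded genes took 2.31%, 2.75% and 3.01% of the counts in the control libraries and 2.48%, 2.39% and 2.48% in the knockdown libraries. Nothing in the labels says that the replicates were separate cultures, so the p-values of single genes measure the spread between these libraries, which may be technical. Camera with the preset correlation sets the members of a list against the other genes. The permutations used for words in 3' UTRs shuffle genes, so they measure the spread between genes and not between libraries.

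The single comparison of the design asks which transcripts change in IL-4-treated macrophages when RP11-184M15.1 is targeted. The level of RP11-184M15.1 itself is not analysed here, because no gene carries that name in the table or the annotation used, and so the knockdown was not checked under that name. Among transcripts with a mean log2 CPM of at least 1, the most reduced was AC078850.1, annotated as a long intergenic noncoding RNA (ENSG00000248187.1, GRCh38 chromosome 4, 128567972 to 128570531, minus strand, overlapping no other annotated gene). It fell from 174 ± 21.3 CPM in the controls (SD, n = 3) to 27.0 ± 2.04 CPM in the knockdown libraries (SD, n = 3), a reduction of 84.5% (log2 fold change -2.69 ± 0.08 SE; edgeR quasi-likelihood adjusted p = 2.28e-11). Its counts were 2106, 1962 and 1664 in the control libraries and 335, 355 and 353 in the knockdown libraries.

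Across the transcriptome the shifts were small. Of 13405 genes tested, 379 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 163 higher and 216 lower in knockdown. The median absolute log2 fold change of these genes was 0.33, 49 of them changed by at least 1.5-fold, and 13 had an absolute log2 fold change of at least 1. The 3 knockdown libraries lay entirely above or below the 3 controls in 375 of the 379 genes (98.9%) and in 20% of all genes tested, where chance gives 10%. The count moved with the libraries used: it was 542, 165 and 488 without control replicates 1, 2 and 3, and 194, 139 and 156 without knockdown replicates 1, 2 and 3.

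**Figure D1:**
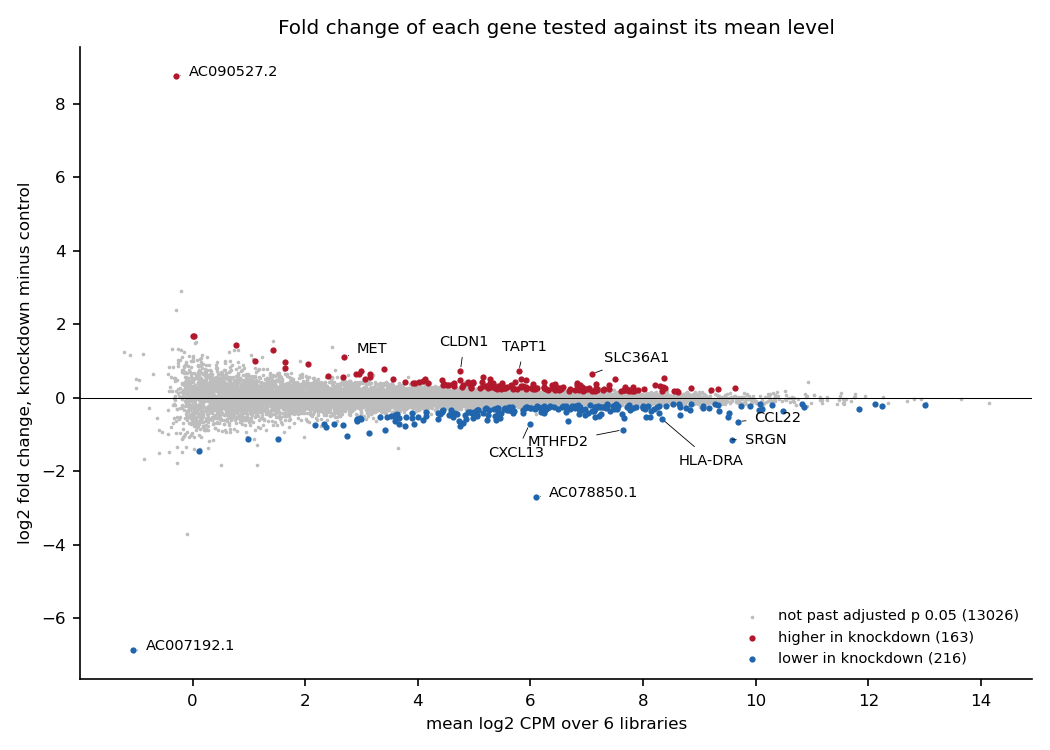
Log2 fold change (knockdown minus control) against mean log2 CPM over the 6 libraries for the 13405 genes tested, with the 163 genes that rose in red and the 216 that fell in blue. AC078850.1 lies at -2.69, away from other genes of its level, and the fitted values of AC090527.2 and AC007192.1 depend on the prior count because a whole group of libraries had 0 counts.

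The 12 genes with the smallest p that fell were AC078850.1 and 11 protein-coding genes. SRGN, the core protein of the granule proteoglycan serglycin, fell from 1140 ± 117 to 517 ± 18.7 CPM (SD, n = 3 each; log2 fold change -1.14 ± 0.06 SE, edgeR adjusted p = 2.67e-08). The IL-4-induced chemokine CCL22 fell from 1029 ± 120 to 658 ± 4.48 CPM, and CCL17, which binds the same receptor, from 315 ± 22.7 to 221 ± 4.61 CPM. The log2 fold change was -0.71 for the B-cell chemokine CXCL13, -0.51 for the chemokine receptor CCR7 and -0.42 for IL10RA, the ligand-binding chain of the interleukin-10 receptor. MTHFD2, a mitochondrial enzyme of one-carbon folate metabolism, fell by 45.2%, from 271 ± 3.07 to 148 ± 1.07 CPM. The others were RDX (radixin, which ties actin to the membrane) at -0.62, PTPRJ (a receptor-type tyrosine phosphatase) at -0.48, BIRC3 (an inhibitor of apoptosis induced by NF-kB) at -0.54 and NR4A3 (an orphan nuclear receptor) at -0.51. All 12 genes that fell and all 12 that rose lay apart from the controls in every library, as the naming rule requires, and each kept its direction and an adjusted p under 0.05 when any 1 library was left out.

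The 12 genes with the smallest p that rose were all protein-coding. SLC36A1, a proton-coupled amino acid transporter, rose from 108 ± 6.44 to 170 ± 1.32 CPM (SD, n = 3 each; log2 fold change 0.65 ± 0.05 SE, edgeR adjusted p = 4.15e-06). MET, the receptor for hepatocyte growth factor, had the largest rise of the 12, from 4.27 ± 0.30 to 9.28 ± 0.07 CPM (log2 fold change 1.12). The tight-junction gene CLDN1 rose by 0.73 and TAPT1 by 0.72 on the log2 scale. CALU, a calcium-binding protein of the endoplasmic reticulum, rose by 0.52, and MBTPS1, the protease that cleaves membrane-bound transcription factors in the Golgi, by 0.43. CCND3 (cyclin D3) rose by 0.55, WSB1 by 0.53, the mitochondrial phosphatase PTPMT1 by 0.57, SMPDL3A by 0.47, the lipid kinase PIP4K2A by 0.43 and YTHDF3, a reader of methylated mRNA, by 0.38.

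**Figure D2:**
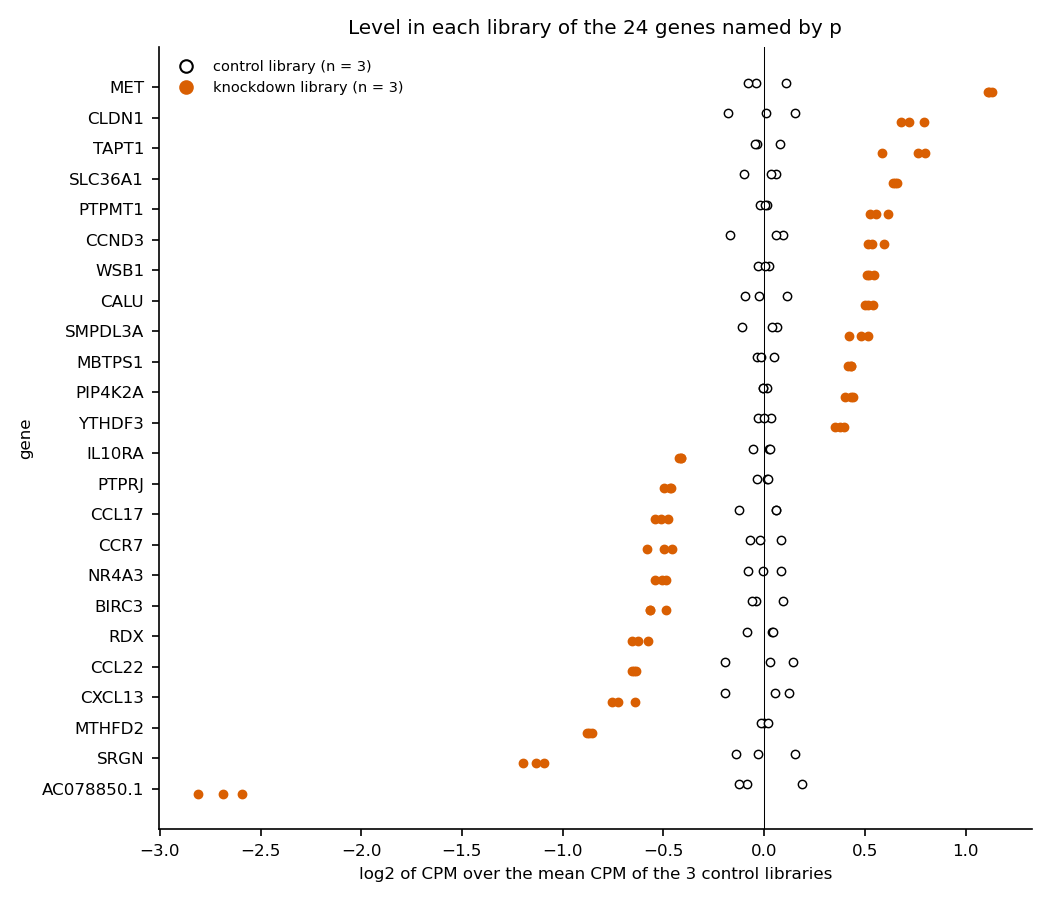
Level of each of the 24 named genes in each library, as log2 of its CPM over the mean CPM of the 3 control libraries (open circles, controls; filled circles, knockdown). Knockdown libraries lie on 1 side of the controls for every gene shown, with AC078850.1 farthest.

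Several of these genes share sequence or position with others. The 7-base word AGGATTA occurs in the annotated 3' UTR of 7 of the 11 genes with a 3' UTR among the 12 that fell (MTHFD2, SRGN, RDX, PTPRJ, NR4A3, IL10RA and CXCL13) and of 2 of the 12 that rose. GACGTA, a 6-base word, occurs in 6 of the 12 that rose and 1 of the 11 that fell. Both words were picked as extremes on these same fold changes, so their presence in these genes is not separate evidence. Of 11034 genes searched, 1300 carried AGGATTA and 522 GACGTA. No source used here says that strand was kept in counting, so counts of genes with another gene on the opposite strand at the same place are less certain (SLC36A1, TAPT1, CCND3, PTPMT1, MTHFD2, RDX and PTPRJ). The same holds for genes that overlap another on their own strand: PTPMT1, which overlaps NDUFS3, and CALU, CCND3, MBTPS1, PIP4K2A, SRGN, RDX and PTPRJ, which overlap pseudogenes, small RNAs or genes with a clone-derived name.

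Of 14 genes of antigen presentation by major histocompatibility complex (MHC) class II, 10 fell and none rose past the threshold over all genes, and 11 fell when adjusted over the list alone. With 1 library left out the count that fell ran from 6 (without knockdown replicate 2) to 11. HLA-DRA fell from 392 to 265 CPM (log2 fold change -0.57 ± 0.07 SE, edgeR adjusted p = 0.000295), HLA-DPB1 had a log2 fold change of -0.71, HLA-DQB1 of -0.56 and HLA-DPA1 of -0.49. Further members, chosen after their values were seen, were CIITA, the coactivator that switches on class II genes (-0.42), and CD74, the invariant chain (-0.33). CIITA's adjusted p was 0.0977 without control replicate 2 and 0.106 without knockdown replicate 2, and that of CD74 was 0.101, 0.0988 and 0.0743 without control replicate 2, knockdown replicate 2 and knockdown replicate 3. Other members were near 0: CTSS had a log2 fold change of -0.05, CD80 of 0.03 and CD86 of 0.02, none past the threshold. The list had a median log2 fold change of -0.46 and an adjusted p of 7.35e-14 in camera with a preset correlation of 0.01, but an adjusted p of 0.161 with an estimated correlation. In the same libraries, lists fixed as signs of RNA quality also lay below 0, with a median of -0.16 for mitochondrially encoded mRNA and -0.11 for cytosolic ribosomal proteins. A link was not tested. HLA-DRB1 (-0.33) and HLA-DRB5 (-0.42), also chosen after their values were seen, are near-identical copies that share reads. Without knockdown replicate 2 their adjusted p was 0.0645 and 0.158, without knockdown replicate 3 it was 0.0531 and 0.0907, and that of HLA-DRB5 was 0.168 without control replicate 2. HLA-DPA1 overlaps HLA-DPB1 on the opposite strand.

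Of 25 targets of IL-4 and its transcription factor STAT6, 5 fell and none rose over all genes, and 8 fell and 2 rose when adjusted over the list alone. With 1 library left out, 2 to 7 fell and up to 2 rose. Besides CCL22 and CCL17, the fatty-acid-binding protein FABP4 had a log2 fold change of -0.37 and the chemokine CCL26 of -0.79, at only 6.57 and 3.84 CPM. FABP4's adjusted p ran from 0.060 to 0.11 without control replicate 2 or any 1 knockdown replicate, and that of CCL26 was 0.156, 0.0928 and 0.159 without control replicate 2, knockdown replicate 1 and knockdown replicate 2. The list's median was -0.18 and its camera adjusted p 0.00067, against an adjusted p of 0.161 with an estimated correlation. With all libraries thinned at random to the lowest total, the median ran from -0.18 to -0.08 over 20 draws, and 3 to 5 members fell. These medians lie beside the -0.16 of mitochondrially encoded mRNA and the -0.11 of cytosolic ribosomal proteins.

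Of 19 genes of macrophage differentiation, 4 rose and none fell over all genes, and 7 rose when adjusted over the list alone. With 1 library left out the count that rose ran from 1, CD14 (without control replicate 2 or knockdown replicate 2), to 5. CD14, the lipopolysaccharide co-receptor, rose from 105 to 133 CPM (log2 fold change 0.34 ± 0.06 SE, edgeR adjusted p = 0.003). The scavenger receptor CD163, with a log2 fold change of 0.40, had adjusted p of 0.0796, 0.0535 and 0.119 without control replicate 2 and knockdown replicates 1 and 2. The list passed in camera (adjusted p = 0.0295) with a median of 0.01 and a mean of 0.07, and it had an adjusted p of 0.411 with an estimated correlation and of 0.232 without knockdown replicate 2. It did not pass in fry (adjusted p = 0.189). Phagocytic and scavenger receptors had 2 of 24 members higher and none lower (7 higher and 4 lower when adjusted over the list alone; 0 to 3 higher and 0 to 2 lower with 1 library left out) and did not pass in camera (adjusted p = 0.0909), but rose in fry (adjusted p = 0.0139), with an adjusted p of 0.261 in camera with an estimated correlation. The 2 receptor genes that rose, CD163 and ITGAX, are also among the 4 of macrophage differentiation, so these lists are not separate evidence. The list of lipid handling below likewise shares members, among them LPL with macrophage differentiation and FABP4 with the IL-4 list. Markers of undifferentiated myeloid progenitors had a median of -0.11 over 9 members, none past the threshold (adjusted p = 0.36).

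Lists of lipid handling, stress response and matrix genes rose in camera with the preset correlation, but had adjusted p of 0.161, 0.161 and 0.176 with an estimated correlation. Of 21 genes of lipid handling by LXR and PPAR receptors, 3 rose and 1 fell, both over all genes and when adjusted over the list alone, with SMPDL3A at 0.47 and FABP4 lower (camera adjusted p = 0.012, and 0.161 with an estimated correlation; median 0.09). With 1 library left out, 1 to 4 rose and 0 or 1 fell. The cholesterol exporter ABCA1 (log2 fold change 0.22) had adjusted p of 0.132, 0.124 and 0.123 without control replicate 2 and knockdown replicates 2 and 3. Genes of the unfolded protein and integrated stress response had 2 of 21 higher and none lower (4 higher and 1 lower when adjusted over the list alone), among them PDIA4, a disulfide isomerase of the endoplasmic reticulum, at 0.25 (camera adjusted p = 0.000616, and 0.161 with an estimated correlation; median 0.10). The other, SESN2 (log2 fold change 0.29, adjusted p = 0.0498), had adjusted p from 0.0583 to 0.248 when any 1 library was left out and did not pass in DESeq2, in limma-voom or with no filter. Matrix, adhesion and tissue-repair genes had 3 of 24 higher and 1 lower (4 and 2 when adjusted over the list alone), and 1 to 4 higher and 1 lower with 1 library left out. MMP1 (0.33) and MMP12 (0.26) had adjusted p of 0.0835 and 0.0531 without knockdown replicate 3, and MMP1 of 0.0508 without knockdown replicate 2. The fibronectin receptor subunit ITGA5 rose by 0.28, while THBS1 (thrombospondin-1) had a log2 fold change of -0.61. That list passed at an adjusted p of 0.0338 with a median of 0.06, and had adjusted p of 0.176 with an estimated correlation, 0.063 without control replicate 3 and 0.104 without knockdown replicate 2.

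Lists of cell cycle, glycolysis and RNA-binding protein genes fell in camera with the preset correlation, but had adjusted p of 0.306, 0.161 and 0.161 with an estimated correlation. Of 27 cell cycle genes 1 fell over all genes and 2 when adjusted over the list alone, and 26 had a log2 fold change below 0, with a median of -0.13 (camera adjusted p = 2.14e-05, and 0.306 with an estimated correlation). Leaving out 1 library gave 0 to 3 cell cycle genes that fell (3 without control replicate 1). The replication helicase subunit MCM2, the member past the threshold, had a log2 fold change of -0.25 and adjusted p from 0.0722 to 0.212 without control replicates 2 or 3 or any 1 knockdown replicate. Glycolysis and hypoxia genes had 3 of 22 lower (4 when adjusted over the list alone), a median of -0.11 and a mean of -0.04 (adjusted p = 0.0142, and 0.161 with an estimated correlation). These were the glucose transporter SLC2A1 (-0.24), ENO1 (-0.18) and LDHA (-0.22), and no member of the list passed without control replicate 2, knockdown replicate 2 or knockdown replicate 3. None of 29 hnRNP and other RNA-binding protein genes passed singly, over all genes or over the list alone, and 23 lay below 0, with a median of -0.08 (adjusted p = 0.000219, and 0.161 with an estimated correlation). Leaving out 1 library gave 0 to 2 RNA-binding protein genes that fell. Lists fixed as signs of RNA quality also had medians below 0, and a link between them and the lists above was not tested. The replication-dependent histones among them did not pass (median -0.09, camera adjusted p = 0.822). Mitochondrially encoded mRNA had 12 of 13 members below 0 (1 past the threshold over all genes, 2 over the list alone; adjusted p = 0.000403, and 0.449 with an estimated correlation and 0.17 without control replicate 3). Cytosolic ribosomal proteins had 28 of 30 below 0 (1 past the threshold over all genes, 3 over the list alone; adjusted p = 1.53e-08, and 0.404 with an estimated correlation). With 1 library left out, 0 to 12 members passed in each of the mitochondrial and ribosomal lists. Their counts differed by library: 12 and 3 fell without control replicate 1, against 1 and 12 without control replicate 3.

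Interferon-stimulated genes had no member of 31 past the threshold over all genes or the list alone, with a median of 0.04. The list's adjusted p was 0.0142, and 0.661 with an estimated correlation, 0.942 without control replicate 3, 0.224 without knockdown replicate 2 and 0.229 without knockdown replicate 3. Genes of NF-kB and inflammation did not pass as a list (adjusted p = 0.364), although BIRC3 and SOD2 (log2 fold change -0.26) fell and NLRP3 (0.24) was the 1 member higher over all genes. NLRP3 had adjusted p of 0.0748, 0.0681 and 0.124 without control replicate 2 and knockdown replicates 1 and 2. The list had 2 higher and 4 lower members of 26 when adjusted over the list alone. Cholesterol synthesis had 1 of 24 genes higher, the sterol oxidase MSMO1 at 0.32, and 2 lower (2 and 2 when adjusted over the list alone), with a list adjusted p of 0.107, which was 0.0434 without control replicate 1. The lower members, HMGCS1 (-0.24) and TMEM97 (-0.39), had adjusted p up to 0.158 and 0.149 with 1 library left out. The lists of p53 targets and apoptosis (adjusted p = 0.443), lysosome (0.922), nuclear oxidative phosphorylation (0.481, and 0.0212 without control replicate 3) and replication-dependent histones (0.822) did not pass. Adjusted over the list alone, 2 of the p53 and apoptosis genes were higher and 1 lower, 1 lysosomal gene was higher and 1 lower, and none of the other 2 lists passed. Markers of lymphoid cells (3 tested) and of epithelial and mesenchymal cells (4 tested) were too few to test as lists, and none passed over all genes or the list alone.

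**Figure D3:**
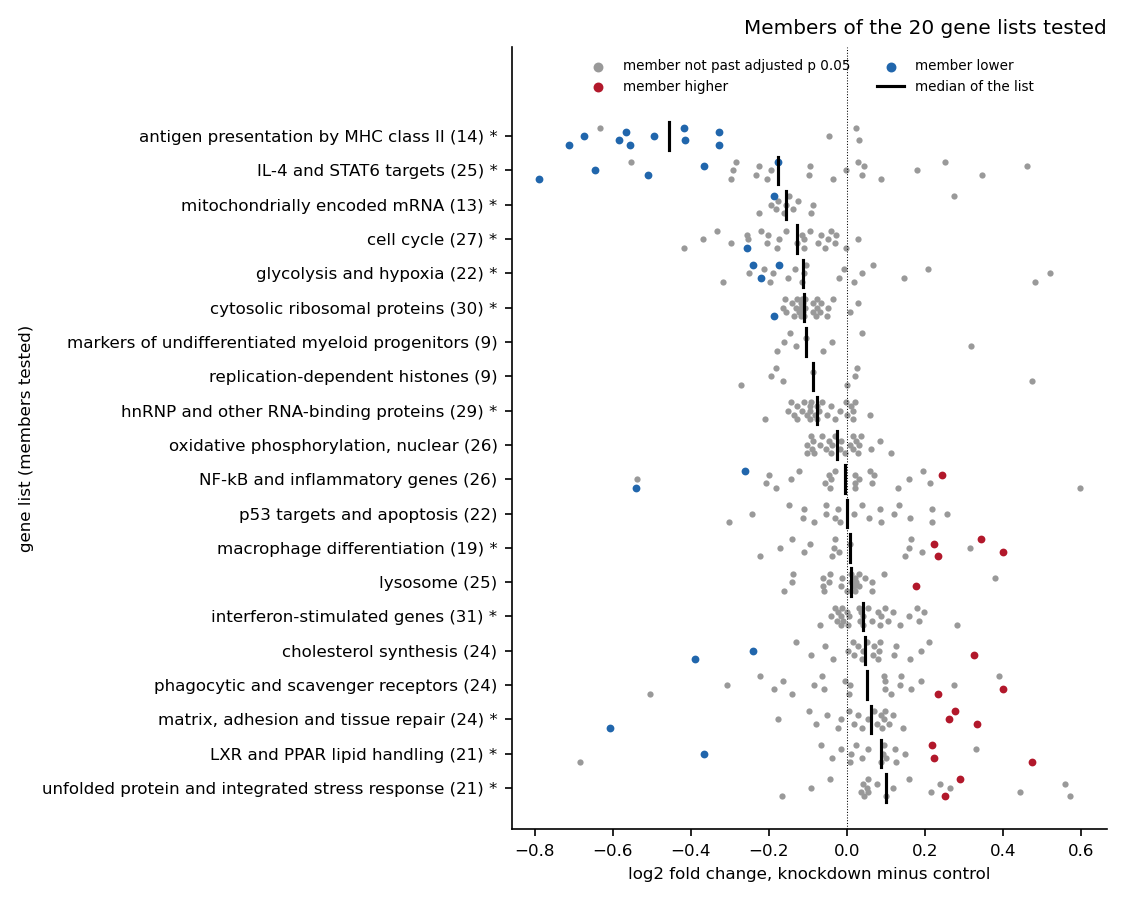
Log2 fold change (knockdown minus control) of each tested member of the 20 gene lists, with the median of each list as a bar and an asterisk where camera with a preset correlation gave an adjusted p under 0.05. The MHC class II list has the lowest median (-0.46), and 10 of its 14 members are past the threshold.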

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

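Leaving out the genes whose 3' UTR holds AGGATTA or GACGTA was chosen after seeing the data, as were the tests by other splits of the libraries; the other alternatives were fixed beforehand. With 1 library left out, calls ran from 139 to 542 (55 to 214 higher, 84 to 328 lower), above and below the 379 of all 6 libraries. They rose only without control replicate 1 (542) or control replicate 3 (488). These controls differed most of any pair within a group, with a chi-square per degree of freedom of 6.79, against 1.90 to 2.28 within knockdown. The cause was not tested. An adjusted p under 0.01 kept 150 genes (56 higher, 94 lower), and an absolute log2 fold change of at least 1 kept 13 (6 higher, 7 lower). Leaving out the 1819 genes with either word gave 212 calls (98 higher, 114 lower) among 11586 genes. DESeq2 called 345 genes, 288 of them shared with edgeR's 379, and no gene called by edgeR changed sign in any alternative fixed beforehand. Of 60 named genes past the threshold, 1, 19 and 4 lost the call without control replicates 1, 2 and 3, and 12, 22 and 19 without knockdown replicates 1, 2 and 3. With an estimated correlation 0 of 20 lists passed, against 12 with the preset value and 8 with fry. In fry, 5 lists past in camera did not pass: cell cycle (fry adjusted p = 0.141), macrophage differentiation (0.189), cytosolic ribosomal proteins (0.189), mitochondrially encoded mRNA (0.395) and interferon-stimulated genes (0.653). The MHC class II (0.0219) and IL-4 (0.0156) lists were among those that passed, and 1 list passed in fry only. A left-out library gave 9 to 13 lists in camera, and leaving out the carriers of either word 14. The replicate numbers were not taken as a pairing: same-numbered libraries correlated at 0.046, 0.10 and 0.083 in their deviations from the group means. Every library correlated best with the library of its own number in the other group, a hint from the data and not from the design, and with the replicate block 488 genes passed (200 higher, 288 lower) and 12 lists. Other splits of the 6 libraries into groups of 3 (10 in all) gave at most 3 genes against 379 and at most 7 lists against 12. Only 1 split, the real one, gave as many in each case, and 10 splits are too few for a share under 0.05. Every other split mixes control and knockdown libraries within a group. The knockdown difference then widens the spread within groups and lowers the calls, so these counts are no measure of chance. Depth limits genes near the floor of 3 counts. The value of RP11-184M15.1 and its neighbours were not run.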

Other observations

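The test of depth for the MHC class II list was fixed before its result was seen. All other tests here were chosen after, including the value used for the single-library test. CCL19, a ligand of CCR7 chosen after its values were seen, fell with its receptor, at a log2 fold change of -0.95 ± 0.13 SE (edgeR adjusted p = 0.000589). STAT6 and IL4R, the transcription factor and the receptor chain behind the IL-4 response and likewise chosen after the fact, had log2 fold changes of -0.06 and -0.07 and did not pass (edgeR adjusted p = 0.606 and 0.623). AC007192.1, an annotated protein-coding gene that overlaps PIK3R2 and IFI30 on 1 strand (chromosome 19, 18153158 to 18178117), had 13, 14 and 13 counts in the controls and 0 in each knockdown library, at least 5.17-fold lower against a floor of 3 counts per library. AC090527.2, which overlaps BLOC1S6 and SQOR (chromosome 15, 45587351 to 45676314), had 0 counts in each control and 18, 74 and 85 in knockdown, at least 16.7-fold higher. Counts of such overlapping genes are uncertain.

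Genes whose 3' UTR holds AGGATTA fell as a class: 1300 of 11034 genes searched carried it, with a median log2 fold change of -0.037 against -0.001 in the other 9734, and 73 were called lower and 13 higher (131 and 144 of the others). A candidate explanation is pairing of the seed of the introduced siRNA, whose sequence is not used here. With the word picked on 1 part of the genes, 3' UTR carriers in the other part were compared with coding-only carriers. These hold the word in the coding sequence and lack its first 6 bases in the 3' UTR. The mean difference was -0.022 over 100 splits (96 of them below 0). The splits reuse the same genes and libraries, so 96 is no measure of chance. These medians were not corrected for 3' UTR length or GC content, so the comparison cannot decide. Coding-only carriers were set against genes without the word in the coding sequence, and both groups lacked even AGGATT in the 3' UTR. The difference of medians was -0.014 and did not pass 0.05 (permutation p = 0.0523). A difference of -0.044 between 8-base and 6-base forms decides nothing, since the word and its longer forms were picked as the lowest on these same fold changes. The length or GC content of the 3' UTR is argued against as the whole cause, since the word had a z of -11.2 before and -12.8 after both were removed. It was the lowest of 16333 words, and the lowest of any word in 1000 permutations was -5.97. The 199 unrelated words of the same bases ran from -2.96 to 2.34, but a word picked as the lowest was bound to lie below them. The shifts were -0.058, -0.032 and -0.016 in the 3 knockdown libraries, against -0.019 to 0.011 in single controls. The shift was thus not confined to 1 knockdown library, although the smallest lies within the control range. All 3 were compared with the same control mean, and each control with the other controls only. These values therefore cannot decide whether 1 control library was the source. Loss of RP11-184M15.1, which the same siRNA was meant to bring about, stays open as an untested biological explanation.

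In 100 random splits of the genes, AGGATTA was the lowest word on the first part in 94, and the chosen word had a mean z of -8.80 on the genes left aside. GACGTA had the highest z of 4096 6-base words (7.34, against at most 5.07 in 1000 permutations). Its 522 carriers had a median log2 fold change of 0.038, with 26 called higher and 9 lower. The median was 0.10 in the 23 genes with at least 2 copies. Among 7-base words, the length used for AGGATTA, the highest z was only 5.28 (GACGTAA). No permutation range for high 7-base words is given, and no split of the genes was run for GACGTA.

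AC078850.1 fell most among transcripts with a mean log2 CPM of at least 1, at a log2 fold change of -2.69, and the next was MSL3P1 at -1.82, which did not pass (edgeR adjusted p = 0.175). A hypothesis is that it is the transcript the siRNA was made against, under another name: its transcript of 1623 bases holds AGGATTA once, at bases 973 to 979 in exon 2 (GRCh38 chromosome 4, 128568616 to 128568622, minus strand). The word alone is weak evidence, being present in 132 of 775 long noncoding genes tested (17.0%), and no table used here links the names. Of the 6 nearest tested protein-coding genes, 3 on each side, none passed: log2 fold changes ran from -0.10 (SCLT1) to 0.11 (ABHD18).

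Of the MHC class II genes 10 of 14 fell, and of the IL-4 targets 5 of 25, and the word in their own 3' UTR is argued against as the direct route, since 1 of the 15 members that fell carried it (6.67%), and the class II median was -0.53 without carriers. The 1 member with AGGATTA is CIITA, with 1 copy, so an indirect route through CIITA may remain for the class II genes and was not tested. Thinning cannot decide whether deeper knockdown libraries were the cause, since it keeps each gene's expected share and the main fit adjusted for library totals. With every library thinned to the lowest total of 10450043 counts, the class II median was -0.457 (-0.456 before). The IL-4 median was -0.177 before, -0.094 in that draw and -0.151 ± 0.031 (SD) over 20 more draws. In each of those 20 the IL-4 list passed in camera with the preset correlation. With an estimated correlation on all counts it did not pass (adjusted p = 0.161). A lower share of differentiated macrophages as a whole is argued against for class II, since general macrophage markers did not fall with it. The class II median lay 0.465 below that of the macrophage differentiation list (0.0082, SD of its members 0.19). That SD is a spread across genes and no error of the median. A change in the share of only some of the macrophages was not tested. A lower share as a whole is not argued against for the IL-4 list, whose median lay 0.185 below. Loss of RP11-184M15.1 and effects of the siRNA on other messages stay open and cannot be separated in these libraries.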
